A study of Mus musculus with 18 samples.

How the data were processed

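Bulk RNA sequencing was done on subcutaneous mouse tumours grown from CT26 cells, CT26-NY-ESO-1 cells or LL/2 cells. CT26 is a colon carcinoma line of BALB/c mice, CT26-NY-ESO-1 (written CT26NYESO1 below) is named for the human tumour antigen NY-ESO-1, and LL/2 is the Lewis lung carcinoma line of C57BL/6 mice. Tumours received OK-432, a penicillin-treated and lyophilised preparation of Streptococcus pyogenes, for 24 hours or no OK-432, and were collected on day 14, per the labels' protocols. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit, per the labels' protocols. The labels name 18 libraries in 6 groups of 3, one group for each tumour type with OK-432 (OK432) and without it (Ctrl). They do not say that the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be partly technical. What the controls were injected with is not given in the sources used here.

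The authors deposited 1 table of TPM values (transcript abundance scaled to the same total in every library) with 55291 genes and 18 libraries, in which each library sums to 1000000. The submitters' processing notes name Trim Galore 0.6.5 (a read trimmer), STAR 2.7.3a (an aligner), StringTie 2.1.2 (a transcript assembler and quantifier) and the genome build mm10. The annotation, the strand setting and the filters are not given in the sources used here. TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval or detection floor is given. TPM is also a share of the library, so a large change in a few abundant genes moves all other values. StringTie can list a gene at exactly 0 where its estimate failed or where reads were assigned to a near-identical copy. Such genes are described only as listed at 0. Gene positions come from GENCODE M21 on the mm10 build, in which 53292 of the table's gene symbols were found.

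Values were analysed as log2(TPM + 1), and every log2 change below is on this scale, which understates the changes of low genes. Genes with a TPM of at least 1 in at least 3 of the 18 libraries were tested, 16816 in all. Differences were tested with limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes shrinkage. One fit of 6 group means, with no covariate, gave all comparisons, so the groups shared 1 estimate of each gene's spread with 12 residual degrees of freedom. The comparisons were OK432 minus Ctrl within each tumour type, the equal-weight average of these 3 effects, the 3 pairwise differences between the effects, and CT26NYESO1 and LL2 controls each against CT26 controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from limma.

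The choices of test, filter, gene lists and alternatives were made before the data were examined. Of 36 gene lists, 35 had at least 3 tested members and entered limma's camera test with a preset correlation of 0.01, adjusted over the lists. The eosinophil list had 1 tested member and was not tested. Camera compares a list with the other genes, and it was also run with the correlation estimated from the residuals. For each list, the mean log2(TPM + 1) of its tested members was taken as a score per library. Scores were compared by two-sided exact permutation tests over 20 assignments within a tumour type, where the smallest possible p is 0.1, and over 8000 assignments across the 3 tumour types, adjusted over the 35 lists. Genes named in the text are the 6 largest called rises and falls with OK-432 in each tumour type. They had an absolute log2 change of at least 1, separated groups and a mean of at least 5 TPM. For the average, the differences between effects and the control comparisons the 5 largest were taken. The average required separated groups in each of the 3 tumour types, and the differences between effects did not require separation. A fixed panel of immune genes and up to 3 called members of each list described, or its first member where none was called, were added. Genes from outside this rule are marked as chosen after their values were seen.

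The procedure was tested on simulated data of the 16816 genes, made from the real tumour means and gene-wise spread. In each tumour type 200 genes were changed, drawn from those with a mean of at least 5 TPM there, averaged on the log2 scale. The proliferation list was raised by 0.5 on the log2 scale. Of the genes changed by 1 on the log2 scale, 93.0% were recovered in the simulated CT26 comparison, 97.0% in CT26NYESO1 and 96.0% in LL2. Of those changed by 2, 99.0% were recovered in each of the 3. The simulation gave every gene normal noise of the size seen in these libraries, the same in all groups. It therefore shows how many such genes the procedure recovers, and not what real tumours or genes under 5 TPM yield. False calls numbered 10 in CT26, 20 in CT26NYESO1 and 16 in LL2. Recovered genes changed by 1 and by 2 numbered 97 and 99 in CT26NYESO1 and 96 and 99 in LL2. In CT26NYESO1 and LL2 the false share of the calls was thus above the adjusted p threshold. Error control at that threshold was therefore not shown by this simulation.

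Alternatives were a pseudocount of 0.1, no filter, a filter at a mean TPM of 5, median-of-ratios and quantile rescaling, fits of only the tumour types compared, the replicate number as a block, array weights, a log2 change of at least 1, an adjusted p under 0.01, limma without trend and robust shrinkage, and leaving out each library in turn. Leaving out genes listed at 0 in some libraries and at 10 TPM or more in others, adding the skeletal muscle score as a covariate and using fry in place of camera were chosen after seeing the data. Plots were drawn in Python 3.11.15.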

Results

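Transcript abundance was measured in 18 tumour libraries, 3 for each of 6 groups, and the libraries parted first by tumour type. The first principal component took 54.0% of the variance and the second 36.0%, while the third took 1.88%. Libraries of the same group correlated at a median Pearson r of 0.992 across genes, which are not independent replicates. Libraries of the same tumour type with and without OK-432 correlated at 0.991, and libraries of different tumour types at 0.894. Each library listed 24036 to 25858 genes above 0. Depth is unknown. Mitochondrially encoded transcripts took 4.31% ± 0.155 of TPM in CT26 controls, 6.27% ± 0.357 in CT26NYESO1 controls and 7.25% ± 0.0783 in LL2 controls (SD, n = 3 each), and 4.48%, 5.99% and 7.22% in the matching OK432 groups.

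The first question was how intratumoral OK-432 changed each kind of tumour after 24 hours. In CT26NYESO1 tumours the largest rises were in neutrophil granule genes and neutrophil-attracting chemokines. S100a9 and S100a8, which encode the 2 subunits of calprotectin, an abundant neutrophil protein, rose by 6.04 ± 0.634 and 4.62 ± 0.617 on the log2 scale (SE; adjusted p = 0.00434 and 0.00954). S100a8 went from 2.25 ± 0.941 TPM in controls to 109 ± 82.5 TPM with OK-432 (SD, n = 3 each), and S100a9 from 1.82 ± 0.12 to 272 ± 209 TPM. Both lie on chromosome 3, S100a8 at 90668978 to 90670035 and S100a9 at 90692632 to 90695721. Cxcl2 and Cxcl3, ligands of the neutrophil receptor Cxcr2, rose by 4.03 and 3.87 (adjusted p = 0.0213 and 0.0217). Lcn2, a siderophore-binding protein of neutrophils and inflamed epithelium, rose by 3.90, and Saa3, an acute phase protein, by 3.82 (adjusted p = 0.0246 and 0.0465). With any 1 library left out S100a9 stayed called, at 5.40 to 7.08. The call of S100a8 ended without control replicate 2 (4.55, adjusted p = 0.0531) or treated replicate 3 (4.28, 0.0706), and that of Cxcl2 without control replicates 2 or 3 or treated replicate 3. Those of Cxcl3 and Lcn2 ended without any 1 CT26NYESO1 control or treated replicate 3, and that of Saa3 without any library but CT26NYESO1 treated replicate 2 or LL2 treated replicate 3. Over all libraries left out Cxcl2 lay at 3.43 to 4.93, Cxcl3 at 3.20 to 4.81, Lcn2 at 3.20 to 4.82 and Saa3 at 3.33 to 4.42, with adjusted p up to 0.151, 0.151, 0.16 and 0.247.

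In total 112 genes were called in CT26NYESO1, 69 higher and 43 lower, of which 32 changed by at least 2-fold, and 2727 had an unadjusted p under 0.05. The lower genes changed little, with 39 of the 43 falling by less than 1.5-fold. The higher share of the calls was 61.6% as deposited, 74.1% after median-of-ratios rescaling and 79.5% after quantile normalization. Of the cytokines on the panel, Il1b rose by 2.90 (adjusted p = 0.0148), from 17.7 ± 4.97 to 158 ± 89.7 TPM, and Csf3r, the receptor of granulocyte colony-stimulating factor, by 1.22 (adjusted p = 0.0462). The call of Il1b ended without control replicates 1 (2.74, adjusted p = 0.061) or 2 (2.85, 0.0606) or treated replicate 3 (2.65, 0.11). That of Csf3r ended in 14 of the 18 refits without 1 library (0.96 to 1.47, adjusted p up to 0.236). Csf3 (1.68, adjusted p = 0.0529), Il6 (1.01, 0.0881) and Nos2 (1.94, 0.0957) did not reach the threshold. Treated and control values overlapped for Il6 and Nos2, and not for Csf3. Differences of 0.01 for Tnf, −0.01 for Ccl2, −0.46 for Ifng and −0.17 for Cd8a were not called. The treated libraries differed widely: S100a8 stood at 183, 19.6 and 123 TPM in replicates 1, 2 and 3. Without treated replicate 2 the calls were 394 higher and 279 lower, without treated replicates 1 or 3 they were 43 and 128 or 3 and 1, without control replicates 1, 2 or 3 they were 10 and 9, 3 and 2, or 16 and 9, and without any 1 library of the other tumour types they were 31 to 76 and 11 to 38. A fit of the 6 CT26NYESO1 libraries alone called 0 genes. The shared estimate of spread averages over groups that differ. The SD of the neutrophil list score was 0.976 in treated CT26NYESO1 libraries and 0.13 to 0.315 in the other groups. For genes like these the shared fit would make the CT26NYESO1 standard errors too small and those of CT26 and LL2 too large.

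**Figure D1:**
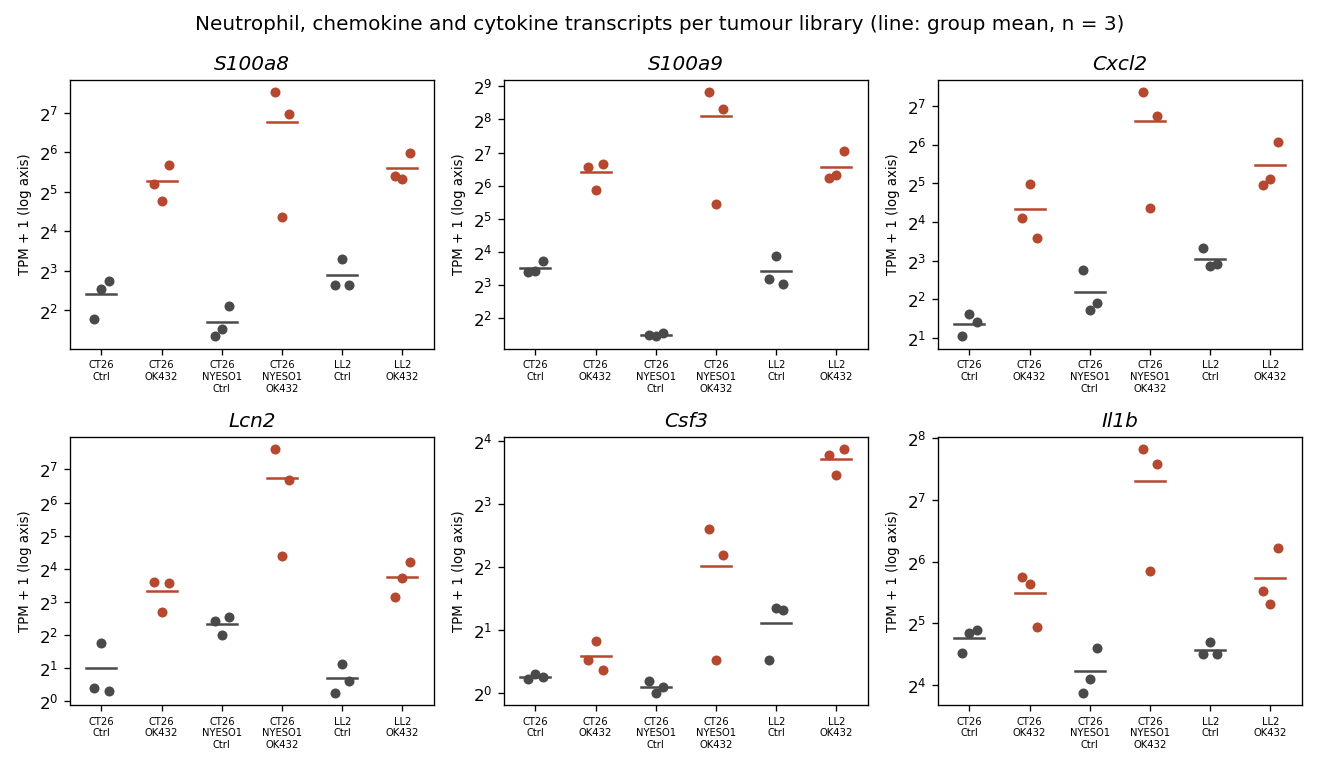
TPM + 1 on a log axis for S100a8, S100a9, Cxcl2, Lcn2, Csf3 and Il1b in each library, with controls in grey, OK-432 in red and a line at the mean of each group of 3. For S100a8 the controls span 1.54 to 8.79 TPM over the 3 tumour types and the treated libraries 19.6 to 183 TPM.

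By gene list, 9 of the 16 tested neutrophil genes and 3 of the 6 neutrophil chemoattractants and growth factors were called higher in CT26NYESO1, and none lower. Adjusted over the list alone, these were 14 and 6. The list medians were 1.89 and 2.94, with camera adjusted p = 4.13e-23 and 2.97e-11. Both had an adjusted p = 0.0933 with an estimated correlation. Proinflammatory cytokines had a median of 0.43 (adjusted p = 1.35e-05, and adjusted p = 0.166 with an estimated correlation), and Il1b and Il1a were called among 11. Acute phase and antimicrobial proteins had a median of 1.61 (adjusted p = 1.56e-05, and adjusted p = 0.275 with an estimated correlation), and Lcn2, Saa3 and Slpi were called among 9. Adjusted over the list alone, each of these lists had 5 members higher. Bacterial pattern recognition and its feedback (median 0.08, adjusted p = 0.000585) had 2 of 20 members called, Zc3h12a, an RNase that limits cytokine transcripts (0.75), and Cd14 (0.63), with 6 higher and 1 lower when adjusted over the list alone. With an estimated correlation this list had adjusted p = 0.495. Camera also called endothelial cells (0.27, 0.000116), hypoxia and glycolysis (0.59, 9.52e-11) and immediate early and heat shock genes (0.51, 5.79e-09) higher. With an estimated correlation these had adjusted p = 0.495, 0.275 and 0.166, and they had no member called over all genes. Adjusted over the list alone, hypoxia had 11 of 15, immediate early genes 10 of 14 and endothelial cells 0 of 13. Interferon-gamma-induced genes (median −0.52, adjusted p = 6.01e-05), proliferation genes (−0.24, 2.69e-08) and mitochondrially encoded genes (−0.13, 0.0153) were lower by camera, with no member called over all genes and, adjusted over the list alone, 0 of 24, 12 of 22 and 1 of 13. These calls were lost with an estimated correlation (adjusted p = 0.73, 0.441 and 0.73). Lists called lower numbered 3, but 10 without control replicate 2, 6 without treated replicate 2 and 5 without treated replicate 1. Pattern recognition was not called without control replicate 2 (median 0.04, adjusted p = 0.0531), nor mitochondrially encoded genes without control replicate 2 (−0.06, 0.278) or treated replicates 1 (−0.11, 0.0726) or 3 (−0.08, 0.0573). While still called, pattern recognition reached 0.14 without control replicate 3 and 0.13 without treated replicate 3, and interferon-gamma-induced genes lay at −0.34 without treated replicate 3. Among single genes, the calls of Slpi and Il1a ended without any 1 control or treated replicate 3 (adjusted p up to 0.151 and 0.184, at 1.82 to 2.64 and 1.42 to 2.19 over all libraries left out). That of Zc3h12a ended without control replicates 1 or 2 or treated replicate 3 (up to 0.151, at 0.63 to 0.86), and that of Cd14 in 11 of the 18 refits (up to 0.214, at 0.49 to 0.78).

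In CT26 tumours no gene was called by limma, and 689 genes had an unadjusted p under 0.05 (362 higher, 327 lower). The smallest adjusted p was 0.377. A fit of the CT26 libraries alone called 3 genes higher and 1 lower, and without CT26NYESO1 treated replicate 2, which enters through the shared spread, 8 were higher. Without CT26 control replicate 2, 1 was higher, and without LL2 treated replicate 1, 1 was lower. The point estimates of the neutrophil genes were still large. S100a8 stood at 4.35 ± 1.69 TPM in controls and 37.5 TPM, ranging from 26.2 to 50.2, with OK-432, a log2 difference of 2.85 ± 0.617 (SE; adjusted p = 0.538). Cxcl2 differed by 2.88 ± 0.626 (adjusted p = 0.538) and Saa3 by 2.54 ± 0.777 (adjusted p = 0.922), while Il1b differed by 0.69, Csf3 by 0.32 and Tnf by 0.15. For S100a8, S100a9 and Cxcl2 every treated library lay above every control. Camera called 5 lists higher: neutrophils (median 0.81, adjusted p = 7.55e-16), neutrophil chemoattractants (0.44, 0.00347), acute phase proteins (0.15, 0.0041), skeletal muscle (1.11, 5.57e-05) and mitochondrially encoded genes (0.06, 0.0242). Adjusted over the list alone, 5 of 16 neutrophil genes, 1 of 6 chemoattractants and 2 of 9 acute phase genes were higher. With an estimated correlation the 5 lists had adjusted p = 0.218, 0.559, 0.559, 0.612 and 0.906. Without treated replicate 1 skeletal muscle (median 0.25, adjusted p = 0.231) and mitochondrially encoded genes (0.04, 0.305) were not called, nor were the latter without treated replicate 3 (0.05, 0.378) or control replicates 1 (0.04, 0.386) or 3 (0.06, 0.0691). While still called, the median of skeletal muscle was 1.74 without treated replicate 3 and that of mitochondrially encoded genes 0.11 without treated replicate 2. That of acute phase proteins was 0.30 and 0.04 without control replicates 2 and 3, and −0.03, 0.25 and 0.54 without treated replicates 1, 2 and 3.

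Camera called 8 lists lower in CT26: type I interferon-stimulated genes (median −0.40, adjusted p = 4.02e-08), interferon-gamma-induced genes (−0.23, 0.00313), natural killer cells (−0.28, 4.92e-06), monocytes (−0.13, 0.00892), mature dendritic cells (−0.19, 0.00656), plasmacytoid dendritic cells (−0.29, 0.0041), regulatory T cells (−0.28, 0.00892) and cytotoxic effectors (−0.23, 0.0449). With an estimated correlation none passed, at adjusted p from 0.218 to 0.906, and adjusted over the list alone at most 1 member of a list was lower. Examples were Ly6c2, a marker of inflammatory monocytes (−1.21, adjusted p = 0.957), and Ncr1, a natural killer cell receptor (−0.23, adjusted p = 1). Without treated replicate 3, 3 lists were lower, as the calls ended for interferon-gamma-induced genes (median −0.12, adjusted p = 0.168), monocytes (−0.07, 0.154), mature dendritic cells (−0.08, 0.12), regulatory T cells (−0.09, 0.459) and cytotoxic effectors (−0.26, 0.261). Without control replicate 3, 5 were lower, as those of interferon-gamma-induced genes (−0.20, 0.0691), regulatory T cells (−0.11, 0.265) and cytotoxic effectors (−0.18, 0.271) ended. Mature dendritic cells were not called without control replicate 1 (−0.29, 0.14), nor cytotoxic effectors without control replicate 2 (−0.10, 0.169). Without CT26NYESO1 control replicate 3 (0.0712) or treated replicate 2 (0.0586), or LL2 treated replicate 3 (0.0509), the call of cytotoxic effectors ended at an unchanged median. While still called, interferon-gamma-induced genes, natural killer cells and regulatory T cells lay at −0.39, −0.45 and −0.42 without control replicate 1, and monocytes and mature dendritic cells at −0.21 and −0.08 without control replicate 3. Skeletal muscle transcripts differed between the CT26 libraries: Acta1, skeletal muscle actin, was 0.142 to 0.617 TPM in controls and 75.9, 10.6 and 0 TPM in treated replicates 1, 2 and 3. With the muscle score as a covariate, 2 lists were called higher and 14 lower.

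In LL2 tumours 3 genes were called and 884 had an unadjusted p under 0.05. Csf3, which encodes granulocyte colony-stimulating factor, rose by 2.65 ± 0.376 (SE; adjusted p = 0.0198), from 1.16 ± 0.631 to 12.2 ± 1.90 TPM. It lies on chromosome 11 at 98701263 to 98703629. Slc13a3, a sodium-coupled dicarboxylate transporter, rose by 1.59 ± 0.227 (adjusted p = 0.0198), from 3.84 ± 0.998 to 14.1 ± 5.63 TPM, and lies on chromosome 2 at 165405028 to 165473230. The third, Eif3j2, encodes a copy of a translation initiation factor subunit in a single exon on chromosome 18 at 43475418 to 43477796. It was at 13.6 TPM on average in controls and was listed at 0 in all 3 treated libraries, while its near-identical copy Eif3j1 was at 50.2 ± 0.819 and 52.6 ± 2.14 TPM. S100a8 differed by 2.71 ± 0.617 (adjusted p = 0.501), from 6.42 ± 2.05 to 47.5 ± 12.8 TPM, Cxcl2 by 2.35 (adjusted p = 0.629) and Il1b by 1.12 (adjusted p = 0.852). The call of Csf3 ended without control replicates 2 (2.79, adjusted p = 0.0619) or 3 (2.77, 0.112), treated replicates 1 (2.61, 0.136), 2 (2.77, 0.061) or 3 (2.56, 0.145), or CT26 control replicate 3 (2.65, 0.0506). That of Slc13a3 ended without control replicate 3 (1.44, 0.182) or treated replicates 2 (1.59, 0.061) or 3 (1.32, 0.106). Instead of 2, no gene was called higher without treated or control replicate 3, and 1 without treated replicate 1 or 2, control replicate 2 or CT26 control replicate 3. Without control replicate 1, 4 were higher and 11 lower, and without CT26NYESO1 treated replicate 2, 12 were higher.

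Camera called 8 lists higher in LL2: neutrophils (median 0.86, adjusted p = 3.09e-18), neutrophil chemoattractants (1.81, 2.74e-12), proinflammatory cytokines (0.21, 0.0119), suppressive myeloid genes (0.19, 0.000553), acute phase proteins (0.40, 0.000497), endothelial cells (0.13, 0.00883), hypoxia and glycolysis (0.19, 3.06e-05) and immediate early genes (0.18, 0.000538). With an estimated correlation none passed, at adjusted p from 0.152 to 0.576. Among them, 7 of 16 neutrophil genes and 5 of 6 chemoattractants passed when adjusted over the list alone. It called 5 lower. Type I interferon-stimulated genes had a median of −1.07 (adjusted p = 2.76e-36), with 0 of 29 members called over all genes and 28 lower when adjusted over the list alone, and adjusted p = 0.174 with an estimated correlation. Ifit1, an antiviral member of that list, was at 33.0 ± 18.1 TPM in controls and 12.1 ± 8.61 TPM with OK-432 (−1.41, adjusted p = 0.715). The others were interferon-gamma-induced genes (−0.78, 1.05e-12), MHC class I (−0.26, 0.000955) and class II presentation (−0.51, 0.0118) and monocytes (−0.13, 0.0319), with Ly6c2 at −1.71 (adjusted p = 0.485). These 4 had adjusted p = 0.475, 0.576, 0.576 and 0.475 with an estimated correlation. Without control replicate 2 the MHC class I median was −0.0722 and camera's direction reversed (adjusted p = 0.986), and MHC class II (−0.23, 0.576), monocytes (−0.17, 0.208) and endothelial cells (0.02, 0.308) were no longer called. Without treated replicate 1 the calls of MHC class II (−0.32) and monocytes (−0.09) ended (0.163 each), and without control replicate 1 that of proinflammatory cytokines (0.12, 0.289). Without treated replicate 3 the calls ended for MHC class I (−0.15, 0.0577), proinflammatory cytokines (0.05, 0.123), immediate early genes (0.05, 0.183), acute phase proteins (−0.16, 0.148), suppressive myeloid genes (−0.01, 0.283) and endothelial cells (−0.04, 0.999). Other medians moved while still called. Without control replicate 1 MHC class I lay at −0.47, MHC class II at −0.77, acute phase proteins at 0.19 and endothelial cells at 0.28. Without control replicate 2 interferon-gamma-induced genes lay at −0.34, and without control replicate 3 acute phase proteins at 0.24. Without treated replicate 1 interferon-gamma-induced genes lay at −0.52, suppressive myeloid genes at 0.31, acute phase proteins at 0.91 and endothelial cells at 0.19. Without treated replicate 2 monocytes lay at −0.24, endothelial cells at 0.24 and hypoxia at 0.32. Lists called higher were 3 without treated replicate 3. Lists called lower were 11 without control replicate 1, 3 without control replicate 2 or treated replicate 1, and 8 without treated replicate 2 or 3 or CT26NYESO1 treated replicate 1.

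**Figure D2:**
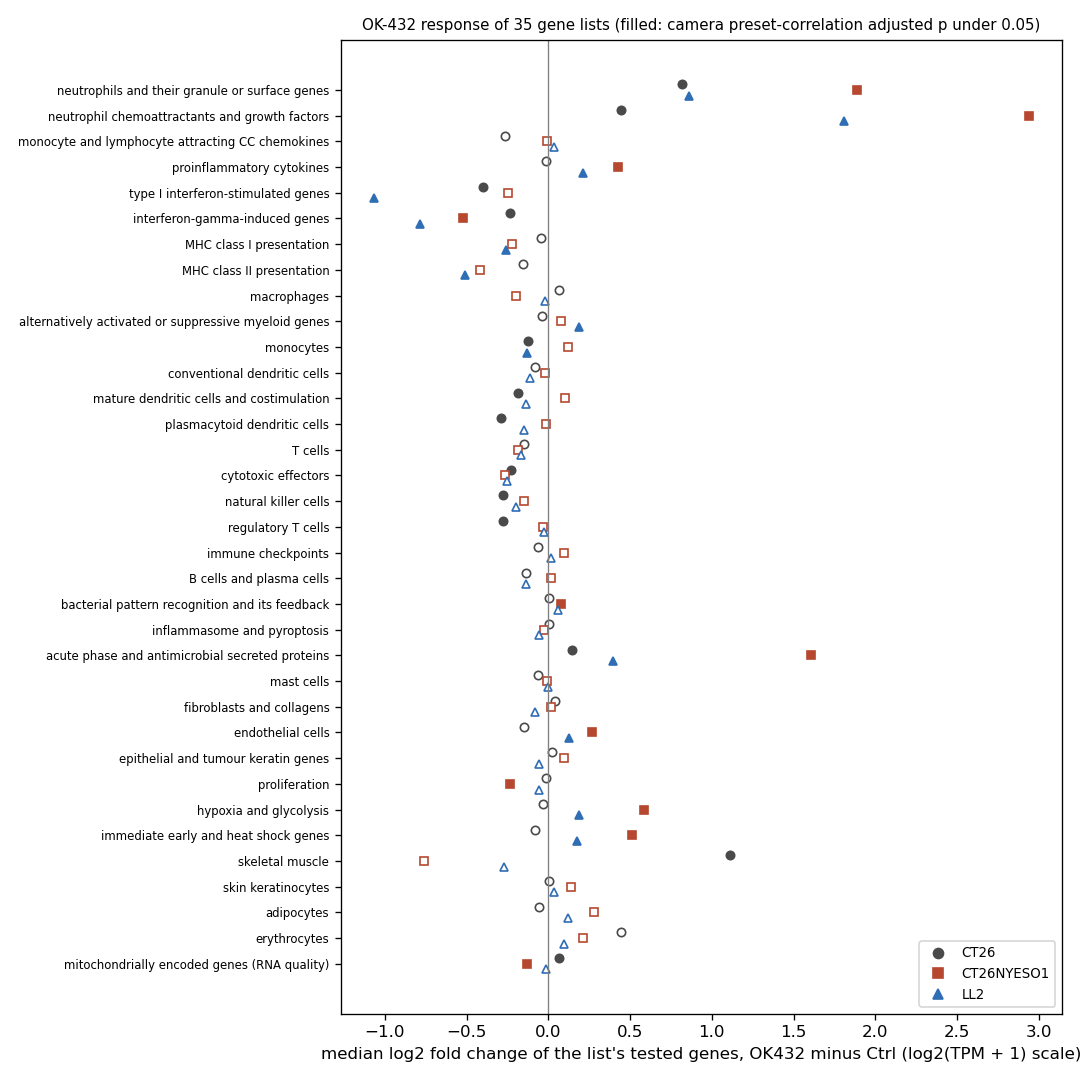
Median log2 change (OK432 minus Ctrl) of the tested members of each of 35 gene lists, in CT26 (grey circles), CT26NYESO1 (red squares) and LL2 (blue triangles), filled where camera with the preset correlation passed. Neutrophil genes lie to the right of 0 in all 3 tumour types, at 0.81, 1.89 and 0.86.

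Averaged over the 3 tumour types, 28 genes were higher and 1 lower, with 1735 at an unadjusted p under 0.05. S100a9 rose by 4.02 ± 0.366, S100a8 by 3.39 ± 0.356, Lcn2 by 3.13 ± 0.379 and Cxcl2 by 3.08 ± 0.361 (SE; adjusted p = 0.000489, 0.00103, 0.00212 and 0.00196). Saa3 rose as well (adjusted p = 0.014), from 4.50, 15.0 and 6.17 TPM in the CT26, CT26NYESO1 and LL2 controls to 31.1, 223 and 49.1 TPM, as did Cxcl3 (2.31, adjusted p = 0.0146) and Csf3r (0.79, adjusted p = 0.0497). Csf3 rose by 1.55, Il1b by 1.57, Il1a by 1.24, Slpi, an antiprotease, by 1.72, and Cd14, a receptor for bacterial products, by 0.38 (adjusted p = 0.00364, 0.0191, 0.00378, 0.0019 and 0.0406). Eif3j2, listed at 0 in treated LL2 tumours as above, was the 1 lower gene. With 1 library left out the call of Csf3r ended in 15 of 18 refits (0.70 to 0.87, adjusted p up to 0.139), that of Cd14 in 15 (0.34 to 0.44, up to 0.119) and that of Il1b in 7 (1.44 to 1.78, up to 0.06). That of Cxcl3 ended without CT26NYESO1 control replicate 2 (adjusted p = 0.0509). Without CT26NYESO1 treated replicate 2 there were 127 higher and 14 lower. Leaving out any other library gave 19 to 29 higher and 1 or 2 lower, except 12 lower without LL2 control replicate 1 and 5 without CT26NYESO1 treated replicate 1. No gene was called in all 3 tumour types, and 5 were without CT26NYESO1 treated replicate 2. At an unadjusted p under 0.05, 21 genes were higher in all 3, where independent lists would share 0.555, and none were lower (0.923).

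The neutrophil list (median 1.12, 8 of 16 members called and 15 adjusted over the list alone) and the neutrophil chemoattractants (median 1.59, 3 of 6 called and 6 adjusted over the list alone) were the 2 lists that passed on average with an estimated correlation (adjusted p = 0.0226 for both). Their per-library scores rose by 1.51 and 1.82. The exact permutation p over 8000 assignments was 0.00025 for each, the smallest possible, with adjusted p = 0.00438 by permutation. Proinflammatory cytokines (0.37, permutation adjusted p = 0.0131) and acute phase proteins (1.03, permutation adjusted p = 0.00583) also passed by score. Scores for type I interferon-stimulated genes (−0.56), interferon-gamma-induced genes (−0.47), natural killer cells (−0.23), conventional dendritic cells (−0.11) and immediate early genes (0.30) did not, each at a permutation adjusted p of 0.0846. With the preset correlation, camera called 9 lists higher and 9 lower on average, interferon-stimulated genes among the latter (adjusted p = 6.58e-22, and 0.28 with an estimated correlation). Scores for macrophages (−0.02), T cells (−0.16), B cells and plasma cells (−0.14), fibroblasts and collagens (0.01), mast cells (0.11), skin keratinocytes (0.08), adipocytes (0.08), erythrocytes (0.24), epithelial keratins (0.05), immune checkpoints (0.01), inflammasome genes (0.10) and CC chemokines (0.15) had permutation adjusted p from 0.139 to 0.939.

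**Figure D3:**
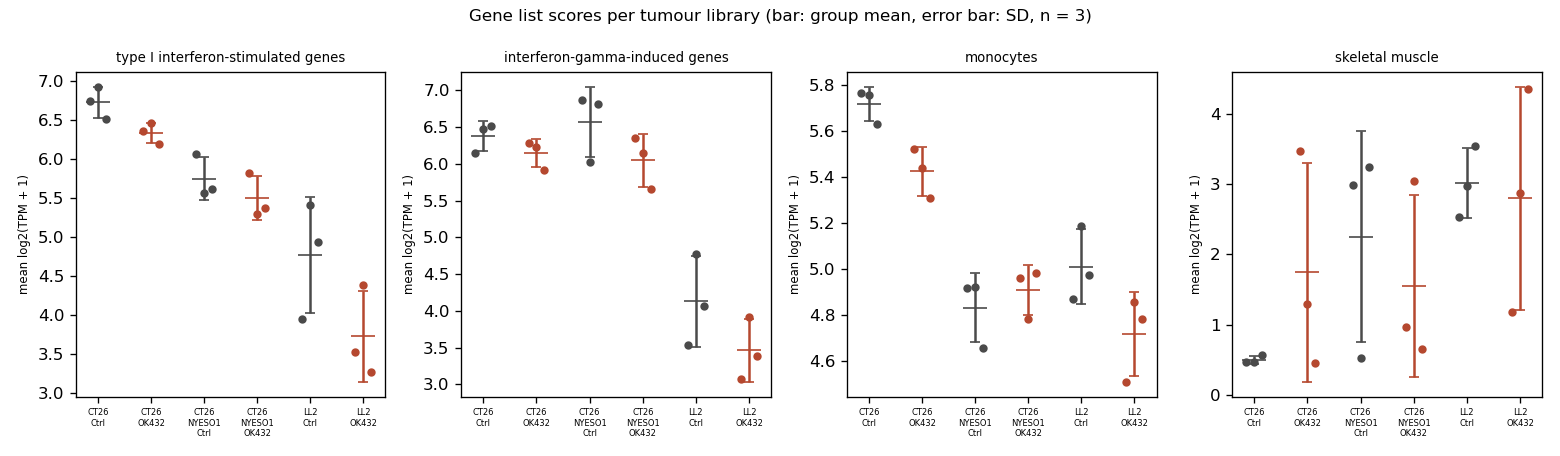
Mean log2(TPM + 1) of 4 gene lists in each library, with controls in grey, OK-432 in red, a bar at the group mean and error bars for the SD of 3 libraries. Type I interferon-stimulated genes stand at 4.77 ± 0.743 in LL2 controls and 3.73 ± 0.583 with OK-432, with overlap between the groups.

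The next question was whether the tumour types responded differently. No gene's effect differed between CT26NYESO1 and CT26 by limma (smallest adjusted p 0.0553, with 1486 genes at an unadjusted p under 0.05). Il1b, called in CT26NYESO1 alone among the tumour types, differed from CT26 by 2.20 ± 0.603 (SE; adjusted p = 0.439), and S100a8 by 1.77 ± 0.873 (adjusted p = 0.582). For LL2 against CT26 and LL2 against CT26NYESO1, 1 gene was called in each case, Eif3j2, with 823 and 1481 genes at an unadjusted p under 0.05. Csf3 differed between LL2 and CT26 by 2.33 ± 0.531 (adjusted p = 0.844). By list, camera with the preset correlation called 11 lists with a higher and 3 with a lower effect in CT26NYESO1 than in CT26, 5 and 3 in LL2 than in CT26, and 1 and 6 in LL2 than in CT26NYESO1. With an estimated correlation none passed, at adjusted p of at least 0.244, 0.903 and 0.691. No member of the lists named here was called over all genes. In CT26NYESO1 against CT26 the median difference was 0.96 for neutrophils (adjusted p = 1.99e-07, and adjusted p = 0.342 with an estimated correlation) and 1.84 for neutrophil chemoattractants (2.57e-06, and adjusted p = 0.244). Of the chemoattractants, 4 of 6 were higher when adjusted over the list alone. Type I interferon-stimulated genes differed by −0.67 in LL2 against CT26 (adjusted p = 3.11e-08, and adjusted p = 0.903 with an estimated correlation) and by −0.80 in LL2 against CT26NYESO1 (1.21e-10, and adjusted p = 0.874). Neutrophil genes differed by −0.82 in LL2 against CT26NYESO1 (2.03e-05, and adjusted p = 0.874 with an estimated correlation). These list differences were not refitted with libraries left out. Without CT26NYESO1 treated replicate 2, 99 effects differed between CT26NYESO1 and CT26, 2 between LL2 and CT26 and 57 between LL2 and CT26NYESO1. Without CT26NYESO1 treated replicate 1 these were 5, 1 and 2, without CT26 control replicate 2 they were 1, 2 and 1, without LL2 treated replicate 1 they were 2, 2 and 1, and without LL2 treated replicate 2 they were 0, 1 and 2.

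The untreated tumours give the background for these effects. Against CT26 controls, CT26NYESO1 controls had 3546 genes higher and 7375 lower. This split depended on scaling: higher genes were 32.5% of calls as deposited, 49.3% after median-of-ratios rescaling and 51.8% after quantile normalization, and the median gene lay at −0.18. The largest rises and falls named here are far from that shift. Smaller differences, such as that of Adgre1 below, are closer to it and can be partly due to scaling. Baiap2l1, an actin-membrane adaptor, was at 6.02 ± 5.45 TPM in CT26 and 781 ± 30.0 TPM in CT26NYESO1 (7.24, adjusted p = 2.11e-06). The other largest rises were Amigo2 (6.65), Clca3a1 (6.04), Ptprn (5.26) and Fst (5.17). Efemp1 and Dkk3, which encode secreted proteins, were at 716 and 242 TPM in CT26, ranging from 683 to 753 and from 220 to 270, and at 2.74 ± 0.886 and 1.61 ± 0.297 TPM in CT26NYESO1. Lrrc17 (−6.73) and Htra1 (−6.33) were lower too, and Rhox2h, at 113 TPM in CT26, was listed at 0 in all 3 CT26NYESO1 controls. On the panel, called genes included Arg1 (higher by 3.22), Ifng (1.49), Cd8a (1.30) and Cd274, which encodes PD-L1 (1.11). Ifit1 was lower, at −1.98 (limma adjusted p = 2.2e-06, 1.56e-05, 0.000649, 0.00558 and 0.00156 in this order). Il12b stood lower in every CT26NYESO1 control, at 0.474 to 0.661 TPM against 1.26 to 1.85 TPM in CT26. So did Adgre1, at 62.1 to 83.1 TPM against 95.5 to 102 TPM. All 13 mitochondrially encoded genes were higher (median 0.49, adjusted p = 8.09e-06), and 12 of 13 endothelial genes were lower (median −2.04, adjusted p = 0.00139). T cell genes (6 of 16 called, all higher, 0.0211), hypoxia genes (10 of 15 higher and 2 lower, 0.0211) and suppressive myeloid genes (8 of 17 higher and 2 lower, 0.0456) were higher by camera. Adjusted over the list alone, the higher genes of these 5 lists numbered 13, 0, 5, 10 and 7, and each list had adjusted p = 0.916 with an estimated correlation. NY-ESO-1 is a human gene and was not analysed here.

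LL2 controls had 4886 genes higher and 6682 lower than CT26 controls, a higher share of 42.2%, or 49.7% and 55.3% after median-of-ratios and quantile rescaling. Tumour line and mouse strain cannot be separated in this comparison. Krt8 and Krt18, keratins of simple epithelia, were at 204 ± 57.4 and 272 ± 40.3 TPM in LL2 and at 0.149 ± 0.0434 and 0.203 ± 0.179 TPM in CT26. Mmp3, a matrix metalloproteinase, was higher by 7.86, Nptx1 by 7.34 and Scara3 by 6.16, and Gbp2b (−7.89), Dkk3 (−7.36) and Rpl39l (−7.05) were lower. Ifi202b, at 225 TPM in CT26, was listed at 0 in all 3 LL2 controls. H2-Ea, an MHC class II gene that C57BL/6 mice do not express, was listed at 0 in all 6 LL2 libraries and ranged from 105 to 517 TPM in the other 12. By camera, 4 immune lists were lower in LL2: 28 of 29 type I interferon-stimulated genes (median −2.06, adjusted p = 0.000199), 23 of 24 interferon-gamma-induced genes (−2.15, 0.000165), 11 of 12 MHC class I genes (−1.41, 0.0104) and 10 of 11 cytotoxic effectors (−1.83, 0.0175), with the same counts when adjusted over the list alone, and each at adjusted p = 0.873 with an estimated correlation. Neutrophil genes and neutrophil chemoattractants were not lower, with medians of 0.28 and 0.96 (adjusted p = 0.476 and 0.612). Endothelial genes were lower as well (11 of 13, 0.0166) and the 13 mitochondrially encoded genes higher (2.53e-05), both at adjusted p = 0.873 with an estimated correlation. Gzmb, a cytotoxic granule protease, was lower by 3.13 and Ncr1 by 2.53 in LL2.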

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

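The tests of blood, scaling, single libraries, macrophages, monocytes, the list score and Eif3j1 were chosen after the results were seen. The bound used for macrophages was revised after its value was seen, and the test of single-exon genes and the counts of other splits were set before.

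The OK-432 effect on Eif3j2 differed between tumour types by limma's interaction test, with −3.78 for LL2 against CT26 (adjusted p = 7.13e-14) and −3.77 for LL2 against CT26NYESO1 (adjusted p = 7.64e-14). These values depend on the pseudocount, because the gene was listed at 0 in all 3 treated LL2 libraries, against a mean of 13.6 TPM in the controls. One candidate explanation is that reads were given to the copy Eif3j1 on chromosome 2 at 122028546 to 122056598. Its gain of 2.43 TPM (95% interval −1.24 to 6.10, from the spread of the 6 values) can be told apart neither from 0 nor from the 5.98 TPM needed. The amount needed rests on 1 annotated transcript of each gene, of 5413 bases for Eif3j1 and 2379 for Eif3j2. A shorter Eif3j1 transcript would need a larger gain, which the interval may not reach. A failed estimate of single-exon genes is also open: among protein-coding genes at 0 in some libraries and at 10 TPM or more in others, 3.08% had a single exon against 1.43% of those that reached 10 TPM and were never at 0 (odds ratio 2.20, 95% interval 0.581 to 5.88, Fisher's exact p = 0.119). An interval that reaches 1 had been set in advance as evidence against it, but with 4 single-exon genes among 130 it also holds several-fold enrichment, so that bound was wrong. The set also holds genes at 0 or near it in all libraries of a tumour type, such as Rhox2h in CT26NYESO1 and Ifi202b in LL2. These need not be failed estimates, so the odds ratio cannot decide the question. A real loss with OK-432 in LL2, the biological explanation, was not tested.

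Kctd12, chosen after its values were seen, was likewise listed at 0 in all 3 LL2 controls and in single libraries of other groups, with 17.7 to 19.5 TPM in treated LL2 tumours. For Il12b every treated CT26 library was below every control and every treated CT26NYESO1 library above every control. The effects differed by 0.67, which limma's interaction test did not call (adjusted p = 0.439), at levels of 0.474 to 1.85 TPM.

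Averaged over the 3 tumour types, neutrophil genes were higher with OK-432 by camera (median 1.12, adjusted p = 0.0226 with an estimated correlation), but in single tumour types the list had adjusted p = 0.218 in CT26, 0.0933 in CT26NYESO1 and 0.166 in LL2 with an estimated correlation. More blood in the treated pieces would raise haemoglobin as much. Hbb-bs, at 62.1 to 105 TPM in the control groups, changed by 0.28 on average (95% interval −0.71 to 1.28). The lower limit for S100a8, among the largest rises, was 2.62, which argues against more blood as the whole cause for that gene. For the list it stays open, because the interval of Hbb-bs holds the list median of 1.12. Scaling or 1 library as the whole cause of the list's rise is argued against, since that median was 1.14 under either rescaling and at least 1.01 with any library left out. Of 100 relabellings of treatment within tumour types, drawn with the real one included, 1, the real one, gave as many calls as the 29 on average, and the highest other gave 26. Chance is therefore unlikely for this count, but with only 100 relabellings drawn it is not excluded. What also stays open is whether neutrophils entered the tumours, which these values would allow, whether blood itself held more neutrophils, or whether other cells made these transcripts.

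Type I interferon-stimulated genes were lower with OK-432 in LL2 by camera with a preset correlation, at a median of −1.07, but adjusted p = 0.174 with an estimated correlation. No single library accounts for that median, which stayed at −0.74 or lower with any library left out, the highest value being that without control replicate 2. Fewer macrophages would lower their markers too, but the macrophage score changed by 0.00723 ± 0.0865 (SE) against −1.04 for the interferon score. Fewer monocytes are not excluded. The monocyte score lay lower with OK-432 in LL2 as well, at a difference of −0.293 ± 0.141 (SE; exact permutation p = 0.1, the smallest possible), and with 2 SE added this passes the bound of 1/2 of the interferon change used for macrophages. Ly6c2, a marker of inflammatory monocytes, was at 14.4 to 58.0 TPM in controls and 5.99 to 11.8 TPM with OK-432. The exact permutation p of the interferon score was 0.2 over 20 assignments, the smallest possible being 0.1, because control replicate 1 (3.95) lay below treated replicate 2 (4.39). Chance, fewer monocytes and a lower interferon response with OK-432 therefore cannot be told apart with 3 libraries a group.

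Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In CT26 the real count was 0, which all 10 splits reach whatever the data, and the highest other was 5. In CT26NYESO1, 1 split, the real one, gave 112 calls and the highest other 18. In LL2, 2 of 10 gave at least 3, the highest other being 10. For CT26NYESO1 and LL2 controls against CT26 controls, 1 split each, the real one, gave 10921 and 11568 calls and the highest other gave 0. For the differences between effects, 100 relabellings were drawn. For CT26NYESO1 against CT26 the real count was 0, which all 100 reach whatever the data, so that count tests nothing (highest other 23). At least as many calls as observed came from 44 for LL2 against CT26 (1 observed, highest other 4) and from 26 for LL2 against CT26NYESO1 (1 observed, highest other 233), so chance is not excluded for these 2. The 233 calls came from 1 relabelling. Treatment was relabelled separately in each tumour type, so a relabelling can reverse it in 1 of the 2. The difference then becomes a sum of the effects, and an effect shared by both tumour types can raise the count. A count far above the real one therefore needs no other structure of the samples, and none was identified or tested. For the same reason the 44 and 26 do not test a difference between effects on its own.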

How the results depend on the processing

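Leaving out genes listed at 0, the muscle covariate and fry were chosen after the data were seen, and the other alternatives were planned. Over all alternatives, tests of named genes were the same in 9655 cases, weaker in 248, stronger in 55 and reversed in 0, and tests of gene lists were the same in 1055, weaker in 88 and reversed in 2. A test counted as the same where it was called in both settings or in neither. Named genes called in neither are thus included, even where their sign changed, so the gene total does not measure how stable the calls were. TPM keeps no depth, so what depth limits is unknown. Except where stated, the cause of a change was not tested. Counts below are given as higher and lower with OK-432.

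With a pseudocount of 0.1, LL2 had 0 genes higher, the average 3 lower, and 2 effects differed between CT26NYESO1 and CT26. With no filter on low values, the counts were 17 and 5 in CT26, 26 and 16 in CT26NYESO1, 10 and 8 in LL2 and 6 lower on average. In that setting 6 effects differed between CT26NYESO1 and CT26, 16 between LL2 and CT26 and 11 between LL2 and CT26NYESO1, with 3 lists higher in CT26 and 5 lower in CT26NYESO1. With a mean TPM of at least 5, LL2 had 0 higher and the average 12 higher, 1 effect differed between CT26NYESO1 and CT26, and 5 lists were lower in CT26. Median-of-ratios rescaling gave 28 lower in CT26NYESO1, 2 lower on average and 1 effect that differed between CT26NYESO1 and CT26. Quantile normalization gave 17, 2 and 1 for the same counts, 5381 genes higher in CT26NYESO1 than in CT26 controls and 8 lists lower in LL2. It shifted the median of all genes in that control comparison from −0.18 to 0.02, and median-of-ratios rescaling shifted it to 0.

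With only the tumour types compared in the fit, degrees of freedom were fewer and the spread was no longer shared with other tumour types. The counts were then 3 and 1 in CT26, 0 and 0 in CT26NYESO1 and 7 and 2 in LL2. Effects that differed numbered 1 (CT26NYESO1 and CT26), 2 (LL2 and CT26) and 3 (LL2 and CT26NYESO1). That setting has no average. Replicate numbers showed no pairing, as same-number correlations across genes ran from −0.05 to 0.04 in CT26, −0.12 to 0.08 in CT26NYESO1 and −0.01 to 0.22 in LL2, and 0, 0 and 1 libraries correlated best with their own number. The replicate block gave 38 and 5 in CT26NYESO1, keeping 31 of 112 calls, 21 lower in LL2, 43 and 55 on average, keeping 26 of 29, and 8 lists lower in LL2. Array weights gave 108 higher in CT26NYESO1, 4 higher in LL2, 50 and 6 on average, 1 effect that differed between CT26NYESO1 and CT26, and 9 lists lower in LL2. An absolute log2 change of at least 1 left 31 and 1 in CT26NYESO1, 894 and 1824 between CT26NYESO1 and CT26 controls, and 1331 and 2453 between LL2 and CT26 controls. An adjusted p under 0.01 left 5 and 3 in CT26NYESO1, 0 higher in LL2, 15 higher on average and 3 lists lower in LL2. Without trend and robust shrinkage CT26NYESO1 had 44 and 12.

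Without the genes listed at 0 in some libraries and at 10 TPM or more in others, LL2 had 1 and 0, the average had 0 lower, and 0 effects differed between LL2 and either other tumour type. The genes left out include Eif3j2 and also Csf3, which was at 0 in CT26NYESO1 control replicate 2. Their calls were thus removed and not tested again. The muscle covariate gave 25 and 11 in CT26NYESO1, 2 lower on average, and 2 and 14 lists in CT26, with the skeletal muscle list itself at a median of −0.0562 in CT26. Fry called 0 and 0 lists in CT26, 4 and 0 in CT26NYESO1 and 0 and 0 in LL2.

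With each library left out in turn, higher and lower genes ranged from 0 to 8 and 0 to 1 in CT26, 3 to 394 and 1 to 279 in CT26NYESO1, 0 to 12 and 1 to 11 in LL2, and 19 to 127 and 1 to 14 on average. Genes higher in all 3 tumour types ranged from 0 to 5, and genes lower in all 3 stayed at 0. Effects that differed ranged from 0 to 99 between CT26NYESO1 and CT26, 1 to 2 between LL2 and CT26 and 1 to 57 between LL2 and CT26NYESO1. Control tumours ranged from 3274 to 3572 and 6871 to 7422 for CT26NYESO1 against CT26, and from 4586 to 4934 and 6275 to 6711 for LL2. Lists ranged from 4 to 5 and 3 to 10 in CT26, 8 to 10 and 2 to 10 in CT26NYESO1 and 3 to 11 and 3 to 11 in LL2. The median log2 change of the list MHC class I presentation in LL2 ranged from −0.467 without control replicate 1 to −0.0722 without control replicate 2, where camera's direction reversed (adjusted p = 0.986).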

Other observations

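The tests of X-linked genes, of shared direction and of muscle were chosen after the patterns were seen, and the reading of the muscle test was revised after its value was seen.

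CT26NYESO1 tumours lacked transcripts that CT26 tumours carried, chosen here after their values were seen. Of 10374 protein-coding genes at 5 TPM or more in every CT26 control, 68 were under 0.5 TPM in every CT26NYESO1 control. Among them were 5 Rhox2 genes, homeobox genes of a cluster on chromosome X. Rhox2h (X, 37668989 to 37673277, mm10) was at 113 TPM in CT26 controls, was listed at 0 in CT26NYESO1 and was at 76.8 TPM in LL2. The imprinted gene Peg10 was at 33.7 TPM in CT26 and at 0.0943 TPM in CT26NYESO1. In the other direction, of 9981 such genes in CT26NYESO1 controls, 36 were under 0.5 TPM in every CT26 control, among them the pluripotency transcription factor Sox2, at 0.118 TPM in CT26, 15.4 TPM in CT26NYESO1 and listed at 0 in LL2. Reads can be shared among the Rhox2 copies, so their single values are uncertain. The ceiling of 0.5 TPM leaves out Baiap2l1, at 756 to 814 TPM in CT26NYESO1 controls. It was at 0.61, 5.92 and 11.5 TPM in CT26 control replicates 1, 2 and 3. Amigo2 rose in the same order, at 0.333, 1.70 and 3.31 TPM, and the reason was not tested. The 68 and 36 genes, and the X-linked shares among them, are therefore not an even comparison of the 2 directions.

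X-linked genes made up 19.1% of the 68 lost genes (13 genes) and 3.17% of the background, an odds ratio of 7.47 (95% interval 3.70 to 14.0, Fisher's exact p = 1.69e-07). Without the Rhox genes it was 4.61 (8 of 63 genes, 95% interval 1.88 to 9.85). Of the 36 gained genes 3 were X-linked (odds ratio 3.09, 95% interval 0.603 to 9.95). One hypothesis consistent with this is that the 2 CT26 lines differ in the state or the number of their X chromosomes. Neighbouring genes are not independent, so the p is too small, and no DNA or methylation was measured here.

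The genes called in CT26NYESO1 tended to move the same way in the tumour types where few or none were called. Of the 69 higher genes, 51 had a positive change in CT26 and 57 in LL2, with medians of 0.10 and 0.23 against 0.77 in CT26NYESO1. Of the 43 lower genes, 24 and 22 had a negative change, with medians of −0.01 and −0.00. The signed mean change over the 112 genes in CT26 and LL2 was 0.35, with an exact two-sided permutation p of 0.005 over 400 relabellings of those libraries, the smallest they can give. The rises may therefore be partly shared, as a hypothesis, and the small falls have no such counterpart in these counts.

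Treated replicate 2 of CT26NYESO1 had the weakest rise of its group and the most muscle transcript (Acta1 71.5 TPM, against 5.65 and 0.664 in treated replicates 1 and 3). If muscle in the tumour piece diluted the response, the treated library with the most muscle should have the lowest S100a8 in each tumour type. It did in 1 of 3. In LL2, treated replicate 3 had the most Acta1 (208 TPM) and the highest S100a8 (62.3 TPM). In CT26, treated replicate 1 had the most Acta1 (75.9 TPM) and an intermediate S100a8 (35.9 TPM). With 3 libraries a group this does not decide whether muscle content may play a part.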
